A study of Drosophila melanogaster with 24 samples.

How the data were processed

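RNA of 8 life-cycle stages of Drosophila melanogaster was measured on two-colour spotted arrays, 3 per stage, each against RNA of 0-4 h embryos as a common reference. Embryos came from 4 h egg lays aged for the stated interval, larvae of different ages were pooled, pupae were picked by stage and adults were collected as males and females, per the labels. Total RNA (20 µg) was labelled indirectly after random priming, hybridized for 16 h at 55 °C, scanned with ScanArray 3.1 and quantified with GenePix 4.0, per the labels. Each probe was spotted 2 times, and hybridizations were kept by a limit on the spread of these duplicates, per the labels. Each stage had at least 1 dye swap, per the labels. Background correction, normalization and the treatment of failed spots are not given in the sources used here.

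The deposited values of 23 arrays were log2 ratios of Cy5 over Cy3 for each of 47616 spots. The scale was read from the values: for a median of 99.99% of the values of an array, 2 raised to the value was a whole multiple of 0.001, and the lowest and highest possible values were the log2 of ratios of 0.001 and 100000. The deposited array medians ran from -1.89 to 2.38, so the values had not been centred. The labels define the ratio as Cy5 over Cy3, and arrays with opposite dyes correlated below 0 in the deposited values (14 of 14 pairs of one stage, 118 of 118 pairs of different stages), so arrays with the stage in Cy3 were multiplied by -1. After this turn 0 of these pairs lay below 0, the lowest at r = 0.051 across probes, which are not independent replicates. Scale, centring and direction were thus settled from the values and labels, while any background step stays unknown. Array c of pupal stage 1 held the log2 of whole numbers from 200 to 29365, a signal of 1 channel rather than a ratio. Its highest absolute correlation with the 23 ratio arrays was 0.102, and it entered no comparison.

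From these values, 633 (0.0578%) at the limits of the scale were set to missing, each array was centred on its median, and the duplicate spots, 1984 positions apart, were averaged to 23808 probes. The design fixed before the data were examined had kept the scaling as deposited and listed centring as an alternative. Once the array medians were seen the 2 were exchanged, so the centred values are the ones reported and the uncentred ones an alternative. No channel intensities were in the table, so no loess fit within arrays, no background limit and no statement on signal over background per probe could be made. Gene symbols came from the platform annotation: 13455 probes had 1 symbol, for 11663 distinct genes, 153 had several and 10200 none. Of the probes with 1 symbol, 12851 matched a current symbol of the RefSeq gene table, and 0 symbols changed. Probes of one gene were kept apart. Where several passed, their signs mostly matched: against the reference, 2 of 55 such genes at 4-8 h and 33 of 382 in adults had probes of opposite sign.

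Differences were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per stage and a probe-specific dye term, over all 23 arrays, which then share 1 estimate of the spread (residual df 14, prior df 5.71). The dye term was needed because each stage had 2 arrays of one dye orientation and 1 of the other, or 2 of the same; it passed for 3632 probes, with a median absolute size of 0.23. A stage was tested against the reference as its coefficient against 0. The labels call the reference a sample made from RNA of 0-4 h embryos; this test leaves out the reference's own spread, and whether 1 preparation served all arrays is not stated. Successive stages were tested as differences of coefficients, and all 8 stages by a moderated F-test over 7 differences. Tests were two-sided, with Benjamini-Hochberg adjustment over 23808 probes and a threshold of 0.05. A total of 36 gene lists was fixed before the files were seen. The 35 lists with at least 5 probes were tested with limma's camera, each against all other probes, in 15 comparisons, adjusted over all 525 tests, with a preset correlation of 0.01 and again with a correlation estimated from the residuals. Of the 525, 240 passed with the preset and 61 of these also with the estimated correlation. Named genes are, per comparison, those with the 10 highest and 10 lowest values among passing probes with 1 symbol, measured on all arrays compared, with one sign on all arrays of the stage (successive stages: no overlap between the arrays), besides the 4 largest members of each list, members that did not pass, and the 10 widest ranges across stages. By this rule the probe named can differ between comparisons, as it does for Lcp65Ag1, Prm, serp, Lsp2, Sgs4 and Vajk4. Genes named as examples outside this rule are said to be so.

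The fit was tested on simulated data with 200 changed probes in each of 8 simulations. Of changes of 2 on the log2 scale, 38% (pupal stage 1) to 72% (8-12 h) were recovered against the reference, 8% (pupal stage 2 against 1) to 24% (pupal stage 3 against 2) between successive stages and 4% to 16% in the F-test. Of changes of 1, at most 10%, 6% and 0% were recovered. Few probes changed in each simulation, so the adjustment was stricter than in the real data. There 1769 (4-8 h) to 8189 probes (adults) passed against the reference and 5011 in the F-test. The recovered shares do not carry over to these comparisons. All 8 lists shifted by 1 were called. In the simulation 0 of 280 unshifted lists were called, which does not hold for the real arrays: there, other groupings of the arrays gave a median of 72 list calls between successive stages with the preset correlation, and of 0 with the estimated one. The number of arrays, 2 or 3 per stage, limits the precision: the median SE of a stage against the reference was 0.43, or 0.55 at pupal stage 1.

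Alternatives planned at the start were the other centring, scaling of the arrays to one spread, no dye term, array weights, a robust prior, other limits on missing values, 1 value per gene, the estimated correlation, a minimum size of change, only the arrays of the stages compared, the replicate letter as a block, and leaving out each array in turn. Added after the data were seen were centring within runs of spots, keeping the limit values, only probes with close duplicate spots, leaving out 5 arrays with unlike duplicate spots, averaging arrays a and b of pupal stages 2 and 3 (which correlated most), and treating as a block or leaving out the 4 arrays that stood apart. The fit of only the arrays of the stages compared had no dye term. The 5 arrays with unlike duplicate spots were a and b of 12-16 h, b of larvae, a of pupal stage 1 and c of adults. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.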

Results

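The series followed RNA levels through the life cycle of the fruit fly Drosophila melanogaster. The 8 stages were embryos of 4-8 h, 8-12 h and 12-16 h, pooled larvae, 3 pupal stages and young adults of both sexes. Each was hybridized on 3 two-colour glass-slide arrays against reference RNA of 0-4 h embryos. Whether 1 preparation of it served all arrays is not stated. A value is the log2 ratio of the stage over that reference, averaged over 2 duplicate spots per probe, for 23808 probes, of which 13455 carried 1 gene symbol. Of the 24 arrays, 23 held ratios and were used. Array c of pupal stage 1 did not, so that stage rests on 2 arrays and every other stage on 3. The arrays' deposited medians lay between -1.89 and 2.38, so each array was centred on its median, and every "rose" or "fell" below is relative to the median probe. Left uncentred, the median over probes was 0.65 at 4-8 h, -0.97 at 8-12 h, -1.60 at 12-16 h, -1.08 in larvae, -1.43, -1.76 and -0.37 at the 3 pupal stages and -0.49 in adults. Values are given as log2 ± SE. The labels speak of independent experiments but do not give the biological origin of the replicates, so the p-values measure the spread between arrays, which may be technical.

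Across the 8 stages, 5011 probes, of 3490 named genes, differed by limma's moderated F-test (adjusted p under 0.05). The widest range of stage means was that of TwdlD, a cuticle protein of the Tweedle family, which ran from 6.48 at 12-16 h to -2.49 in adults (range 8.97). Eig71Ee, an ecdysone-induced gene of the late larval salivary gland, ran from 7.18 in larvae to -1.70 at 12-16 h (range 8.89). TpnC41C, a troponin C of adult muscle, ran from -0.11 at 12-16 h to 8.19 in adults (range 8.30). Lsp2, which encodes a larval serum storage protein, and Scp1, a sarcoplasmic calcium-binding protein, had ranges of 8.28 and 7.89. Further wide ranges were those of nur (8.42), the cuticle genes Acp65Aa (8.15) and TwdlN (7.82), and EAChm (7.68). Of probes with 1 gene, 27.7% differed among the stages, against 12% of the 10200 probes with none. The ratio of these shares, 2.305, was 1.442 uncentred and 1.314 with close duplicate spots. Without centring 9757 probes passed the F-test. Without the dye term 3335 passed, and 3174 with arrays a and b of pupal stages 2 and 3 averaged.

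**Figure D1:**
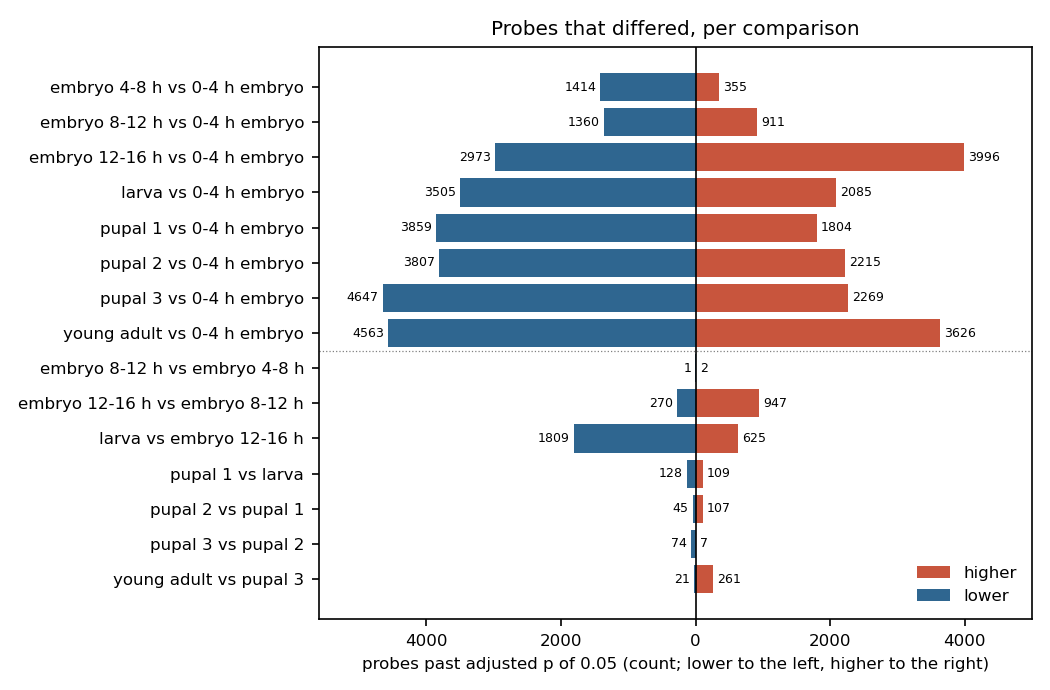
Number of probes past an adjusted p of 0.05 per comparison, higher to the right and lower to the left of 0; the 8 upper bars are stages over the 0-4 h embryo reference and the 7 lower bars successive stages. In the centred values the counts against the reference ran from 1769 at 4-8 h to 8189 in adults, and between 8-12 h and 4-8 h embryos 3 probes passed.

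Embryos of 4-8 h were compared with the 0-4 h reference. Genes of the Lcp65A cluster, which encode larval cuticle proteins, held most of the highest values. Lcp65Ag1 rose by 3.52 ± 0.43 (n = 3 arrays, adjusted p = 5.54e-05), Lcp65Ac by 3.16 ± 0.46 and Lcp65Ad by 3.08 ± 0.42. LanA, a laminin chain of basement membranes, rose by 2.99 ± 0.51. Of the 10 probes for larval cuticle proteins, 7 rose, 0 fell and 3 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 1.67e-09, or 0.0109 with an estimated correlation). Transcripts known as maternal or early embryonic fell: dhd, a thioredoxin of the female germ line, to -5.17 ± 0.49, Z600, an inhibitor of mitosis in the early embryo, to -4.98 ± 0.47, BigH1, the embryonic linker histone, to -4.83 ± 0.84, and the ovarian gene otu to -3.89 ± 0.40. Of 27 probes for maternal germ plasm and axis genes, 12 fell and 0 rose, with 15 falling when adjusted over the list alone (adjusted p = 1.19e-09, or 0.0143 with an estimated correlation). Among them smg, a repressor of maternal messages, fell to -3.72 ± 0.47, exu, which helps to localize bicoid RNA, to -3.19 ± 0.30, and osk, which assembles the germ plasm, to -2.93 ± 0.78. In the list, tor was at -0.99 ± 0.78 and did not pass, but did with the 4 arrays named next as a block (-3.45, adjusted p = 0.00435). That gain adds no support, as tor is among the probes that set these 4 arrays apart. Arrays a and b of this stage, a of 8-12 h and a of larvae stood apart: 72 probes lay within 1 of 0 on these 4 and on no other array, among them tor at 0.42 on these 4 against -3.51 elsewhere, and slam, needed for cellularization, at -0.38 against -5.16. The 4 arrays also had the narrowest spread of values of all ratio arrays. By limma 1769 probes passed, 355 higher and 1414 lower. The count was 720 without array a, 764 without b and 331 without c, 1032 with those 4 arrays as a block, 16 with only the arrays of this stage, and 125 without those 4, which leaves array c alone with a spread borrowed from other stages. On array c alone BigH1 was at -5.78, LanA at 2.77, Lcp65Ac at 2.98, Lcp65Ad at 2.63 and Lcp65Ag1 at 3.49 without passing, and the call of osk ended uncentred or without any 1 of the 3 arrays. In the deposited, uncentred values 198 probes passed, of which 83.3% were higher, against 20.1% after centring.

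At 8-12 h LanA had the highest value of the named genes against the reference, 4.81 ± 0.51 (n = 3 arrays, adjusted p = 9.67e-06), with LanB1, a second laminin chain, at 3.56 ± 0.54. Pvr, the fly receptor of the PDGF and VEGF family, rose by 4.10 ± 0.73, Con, a cell-adhesion protein, by 3.88 ± 0.45, and apolpp, the lipoprotein precursor of the fat body, by 3.79 ± 0.36. Z600 fell to -5.48 ± 0.47, dhd to -5.42 ± 0.49, osk to -4.55 ± 0.78 and halo, which directs lipid droplet movement in the blastoderm, to -5.23 ± 0.55. Of 37 probes for DNA replication and cell cycle genes, 22 fell, 0 rose and 15 did not pass, with 29 falling when adjusted over the list alone (adjusted p = 8.01e-20, or 0.00675 with an estimated correlation). They included twe, a Cdc25 phosphatase, at -2.89 ± 0.39, the spindle checkpoint gene mad2 at -2.85 ± 0.56 and the securin gene pim at -2.56 ± 0.52. Of 29 probes for proteasome subunits 13 fell and 0 rose, 23 falling when adjusted over the list alone, with Prosalpha5 at -2.38 ± 0.29 (adjusted p = 3.45e-16, or 0.027 with an estimated correlation). The maternal list again had 12 of 27 lower (16 when adjusted over the list alone), and 7 of 10 larval cuticle probes were higher, also when adjusted over the list alone (adjusted p = 0.0143 and 0.0464 with an estimated correlation). In all, limma called 2271 probes, 911 higher and 1360 lower. Leaving out array a, b or c gave 1280, 1160 or 863, and the set of 4 arrays named above, which holds array a, gave 2776 as a block and 1251 when left out, while the arrays of this stage alone gave 521. Of 3084 uncentred calls 1.82% were higher, against 40.1% after centring.

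In 12-16 h embryos the highest values included cuticle genes. Cpr51A, a chitin-binding cuticle protein, rose by 7.16 ± 0.43 (n = 3 arrays, adjusted p = 2.31e-09), the Tweedle genes TwdlN, TwdlM and TwdlD by 6.77 ± 0.59, 6.61 ± 0.67 and 6.48 ± 0.51, Lcp65Ag1 by 6.63 ± 0.43 and Osi14, of the Osiris family, by 6.20 ± 0.39. Tig, the integrin ligand tiggrin, rose by 6.36 ± 0.48. Larval cuticle proteins rose for 7 of 10 probes and fell for 1, also 7 and 1 when adjusted over the list alone (adjusted p = 0.000118, but 0.0706 with an estimated correlation). Of 21 probes for chitin and cuticle formation enzymes 17 rose, 1 fell and 3 did not pass, and 18 rose when adjusted over the list alone, with the chitin deacetylase gene serp at 5.71 ± 0.36 and Tb at 4.37 ± 0.40 (adjusted p = 8.58e-11, or 0.0229 with an estimated correlation). Muscle structural genes were higher for 28 of 33 probes and lower for 0, 28 when adjusted over the list alone, among them Prm (paramyosin) at 6.10 ± 0.40, up (troponin T) at 5.73 ± 0.64 and sls, a titin-like protein, at 5.53 ± 0.51 (adjusted p = 6.8e-18, or 0.0218 with an estimated correlation). Pupal and adult cuticle proteins rose for 10 of 14 probes, 10 when adjusted over the list alone, with 4 not passing; Ccp84Ad and Ccp84Ag stood at 4.18 ± 0.43 and 4.09 ± 0.47 (adjusted p = 2.12e-05, or 0.0128 with an estimated correlation). Neuronal function genes rose for 21 of 46 probes and fell for 1, 22 and 1 when adjusted over the list alone, with nrv2 at 3.67 ± 0.29 (adjusted p = 4.11e-05, but 0.0803 with an estimated correlation); with close duplicate spots alone this list call also ended. On the lower side dhd fell to -6.20 ± 0.49, slam to -6.05 ± 0.66 and osk to -5.98 ± 0.78. Cell cycle genes were lower for 32 of 37 probes (34 when adjusted over the list alone), with twe at -4.68 ± 0.39 and CycE at -4.20 ± 0.50, and proteasome subunits for 26 of 29 (27 when adjusted over the list alone), at adjusted p = 0.00675 and 0.0388 with an estimated correlation. By limma 6969 probes passed, 3996 higher and 2973 lower, against 2110 with only the arrays of this stage. Arrays a and b were among the 5 with unlike duplicate spots. Uncentred, 14518 passed and 4.46% of them were higher, against 57.3%.

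Pooled larvae showed high values for storage, glue and digestive genes. Eig71Ee rose by 7.18 ± 0.47 (n = 3 arrays, adjusted p = 9.51e-09), Lsp2 by 7.12 ± 0.42 and Fbp1, a fat body receptor for serum proteins, by 5.95 ± 0.33. The salivary glue genes Sgs4 and Sgs7 rose by 6.04 ± 0.73 and 5.68 ± 0.55, and 14 of 22 probes of the glue list rose while 0 fell, 14 also when adjusted over the list alone (adjusted p = 1.52e-08, or 0.00938 with an estimated correlation). Digestive enzymes rose for 35 of 48 probes and fell for 0, with 39 when adjusted over the list alone: the Jonah proteases Jon65Aiv, Jon99Cii and Jon66Ci stood at 5.49 ± 0.50, 5.23 ± 0.47 and 4.87 ± 0.42 (adjusted p = 5.5e-20, or 0.00675 with an estimated correlation). Serum and fat body proteins rose for 7 of 9 probes, 7 when adjusted over the list alone, and the larval cuticle gene Lcp1Psi by 5.66 ± 0.43 (list adjusted p = 0.0103 with an estimated correlation). Muscle genes were higher for 26 of 33 probes and larval cuticle proteins for 7 of 10, or 28 and 7 when adjusted over the list alone (adjusted p = 0.0373 and 0.0464 with an estimated correlation). Among the lowest were dhd at -6.09 ± 0.49, Z600 at -5.96 ± 0.47 and Klp67A, a mitotic kinesin, at -4.93 ± 0.40. Cell cycle genes fell for 29 of 37 probes (31 when adjusted over the list alone), including mad2 at -4.67 ± 0.56 and PCNA, the replication clamp, at -3.61 ± 0.42, and maternal genes for 14 of 27 (17 when adjusted over the list alone), including aub at -4.05 ± 0.44 (adjusted p = 0.00675 and 0.048 with an estimated correlation). Over all probes limma called 5590, with 2085 higher and 3505 lower. Without array b there were 3568 and without c 3179; array a belongs to the set of 4 arrays that stood apart. With only the 3 larval arrays and no dye term limma called 0 probes (6078 at an unadjusted p under 0.05). That fit left out both the dye term and the spread shared over all stages. Dropping only the dye term ended no call against the reference of a gene named here. These named calls thus rest on the shared spread. Uncentred, 7727 passed with 2.69% higher, against 37.3%.

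Pupal stage 1 kept high values for serum and glue genes. Lsp2 rose by 7.77 ± 0.54 (n = 2 arrays, adjusted p = 2.74e-08), Eig71Ee by 6.76 ± 0.60, Sgs7 by 6.71 ± 0.71, Fbp1 by 6.61 ± 0.43 and Eig71Ea by 6.33 ± 0.66. The glue list was higher for 15 of 22 probes and lower for 0, 15 when adjusted over the list alone (adjusted p = 1.43e-09, or 0.00675 with an estimated correlation), and serum and fat body proteins for 6 of 9, also 6 when adjusted over the list alone (adjusted p = 3.27e-07, or 0.0162 with an estimated correlation). Obp99b, an odorant-binding protein, rose by 6.36 ± 0.91, and the cuticle gene Vajk4 by 6.11 ± 0.49. gcl, needed for germ cell formation, fell to -6.55 ± 0.65, Pxt, a peroxidase-family gene of the ovary, to -6.49 ± 0.80 and osk to -6.15 ± 0.99. Cell cycle genes fell for 26 of 37 probes (31 when adjusted over the list alone), with CycE at -4.76 ± 0.63 and CycB at -4.62 ± 0.64 (adjusted p = 0.0135 with an estimated correlation). Cytosolic ribosomal proteins were lower for 22 of 37 probes and higher for 0, or 25 and 1 when adjusted over the list alone, with RpS20 at -2.68 ± 0.45 (adjusted p = 3.71e-07, but 0.119 with an estimated correlation). The call of RpS20 ended without array a. Array a had the widest spread of duplicate spots of all ratio arrays, with a median SD of 0.838. By limma 5663 probes passed, 1804 higher and 3859 lower. The count was 2078 without array a, where the lone array b is assumed to vary like the other stages, 730 with only the 2 arrays of this stage, and both arrays had the stage in Cy5. Uncentred, 8375 passed and 1.96% were higher, against 31.9%.

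By pupal stage 2 muscle genes stood among the highest. TpnC41C rose by 6.60 ± 0.34 (n = 3 arrays, adjusted p = 2.14e-10), TpnC4, a troponin C of flight muscle, by 6.42 ± 0.55 and Scp1 by 6.12 ± 0.62. All 33 probes of the muscle list rose, also when adjusted over the list alone (adjusted p = 2.08e-31, or 0.00675 with an estimated correlation). The 2 probes of Lsp2 were at 7.68 ± 0.40 and, for the probe given at the earlier stages, 6.58 ± 0.42, Fbp1 at 6.81 ± 0.33, and 5 of 9 serum and fat body probes rose, 5 with 1 falling when adjusted over the list alone (adjusted p = 0.0174 with an estimated correlation). The cuticle genes Acp65Aa and Cpr49Ah rose by 6.86 ± 0.71 and 6.37 ± 0.38. Of 74 probes of the Cpr family of chitin-binding cuticle proteins, 40 rose, 1 fell and 33 did not pass, 42 and 4 when adjusted over the list alone (adjusted p = 7.46e-15, or 0.00675 with an estimated correlation), and cuticle formation enzymes rose for 14 of 21 (16 with 1 falling when adjusted over the list alone), including y (yellow) at 3.82 ± 0.38 (adjusted p = 0.0343 with an estimated correlation). Testis genes rose for 19 of 35 probes and fell for 2, 21 and 2 when adjusted over the list alone, with dj at 4.34 ± 0.48 and the sperm chromatin gene ProtA at 3.97 ± 0.55 (adjusted p = 9.72e-08, or 0.0143 with an estimated correlation), a list call that ended with the probes whose duplicate spots were close. Phototransduction and eye genes rose for 11 of 21 and fell for 1, 11 and 2 when adjusted over the list alone, with eys at 3.03 ± 0.53 (adjusted p = 1.61e-05, or 0.00675 with an estimated correlation). The yolk protein gene Yp2 was at 4.39 ± 0.32 and Yp1 at 3.73 ± 0.64. Cell cycle genes fell for 32 of 37 probes (34 when adjusted over the list alone), with PCNA at -3.99 ± 0.42 (adjusted p = 0.00675 with an estimated correlation). Uncentred, eys did not pass. Limma called 6022 probes, 2215 higher and 3807 lower, with 3791 left without array a and 3637 without b. Arrays a and b correlated at 0.904, and averaging them and those of pupal stage 3 left 3445. Uncentred, 16603 passed and 1.59% were higher, against 36.8%.

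Pupal stage 3 was led by flight muscle genes. TpnC4 rose by 6.49 ± 0.55 (n = 3 arrays, adjusted p = 7.31e-08), fln, the thick-filament protein flightin, by 6.34 ± 0.40, TpnC41C by 6.31 ± 0.34, the myosin light chain gene Mlc1 by 5.27 ± 0.60 and Obsc, the obscurin gene, by 5.12 ± 0.56. All 33 muscle probes rose, also when adjusted over the list alone (adjusted p = 6.84e-28, or 0.00756 with an estimated correlation). ple, the tyrosine hydroxylase that feeds dopamine and cuticle pigment synthesis, rose by 5.51 ± 0.34, Acp65Aa by 5.57 ± 0.71 and EbpIII, an ejaculatory bulb protein, by 5.02 ± 0.33. Phototransduction genes rose for 9 of 21 probes and fell for 0, 10 and 0 when adjusted over the list alone, with the arrestin gene Arr2 at 2.50 ± 0.41 (adjusted p = 0.000192, or 0.0109 with an estimated correlation). Maternal genes fell for 16 of 27 probes and rose for 0, 17 and 0 when adjusted over the list alone, with smg at -4.45 ± 0.47 and Tl at -4.38 ± 0.28 (adjusted p = 7.95e-07, or 0.0388 with an estimated correlation). Cell cycle genes fell for 31 of 37 (32 when adjusted over the list alone), among them CycB at -4.53 ± 0.50 and RnrL, a ribonucleotide reductase subunit, at -4.46 ± 0.40 (adjusted p = 0.00834 with an estimated correlation). Ribosomal proteins were lower for 27 of 37 probes, 28 with 1 higher when adjusted over the list alone, with RpS18 at -2.26 ± 0.35 (adjusted p = 1.52e-08, but 0.0838 with an estimated correlation). Limma called 6916 probes, 2269 higher and 4647 lower. Arrays a and b correlated at 0.892, and averaging them and those of pupal stage 2 left 4368. Uncentred, 4267 passed and 9.59% of them were higher, against 32.8%.

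Young adults, collected as males and females, had high values for muscle, eye and male reproductive genes. TpnC41C rose by 8.19 ± 0.34 (n = 3 arrays, adjusted p = 8.15e-12), Scp1 by 7.56 ± 0.62, fln by 7.22 ± 0.40, ple by 6.71 ± 0.34, EbpIII by 6.44 ± 0.33 and BomBc2, a Bomanin immune peptide, by 6.79 ± 0.59. All 33 muscle probes rose, also when adjusted over the list alone (adjusted p = 3.05e-29, or 0.00675 with an estimated correlation). Phototransduction genes rose for 13 of 21 probes and fell for 0, 15 and 0 when adjusted over the list alone, with Arr2 at 5.14 ± 0.41 and the visual G protein gene Gbeta76C at 4.98 ± 0.34 (adjusted p = 1.79e-07, or 0.00655 with an estimated correlation). Male accessory gland proteins rose for 11 of 18 and fell for 1, 12 and 1 when adjusted over the list alone, led by Acp36DE at 5.52 ± 0.44 (adjusted p = 1.82e-05, or 0.00675 with an estimated correlation), and testis genes rose for 19 of 35 and fell for 3, 20 and 3 when adjusted over the list alone, led by Mst84Da at 5.13 ± 0.32 (adjusted p = 0.0255 with an estimated correlation). The testis list call ended with the probes whose duplicate spots were close. Digestive enzymes rose for 31 of 48 (32 when adjusted over the list alone), with Amy-p, an amylase, at 4.99 ± 0.65, and odorant-binding proteins for 18 of 42, 18 when adjusted over the list alone, with Obp57c at 5.21 ± 0.44 (adjusted p = 0.0221 and 0.0296 with an estimated correlation). Yp2 rose by 6.22 ± 0.32. Oxidative phosphorylation genes were higher for 33 of 37 probes and lower for 0, 34 and 0 when adjusted over the list alone, with ATPsynbeta at 2.63 ± 0.30 (adjusted p = 8.58e-13, but 0.0634 with an estimated correlation). Cell cycle genes fell for 35 of 37 probes, 35 when adjusted over the list alone, with pim at -4.37 ± 0.52 (adjusted p = 0.00675 with an estimated correlation), and halo and Z600 were at -6.18 ± 0.55 and -5.95 ± 0.47. By limma 8189 probes passed, 3626 higher and 4563 lower. With only the probes whose duplicate spots were close, 5442 passed. Uncentred, 5704 passed with 22.6% higher, against 44.3%.

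**Figure D2:**
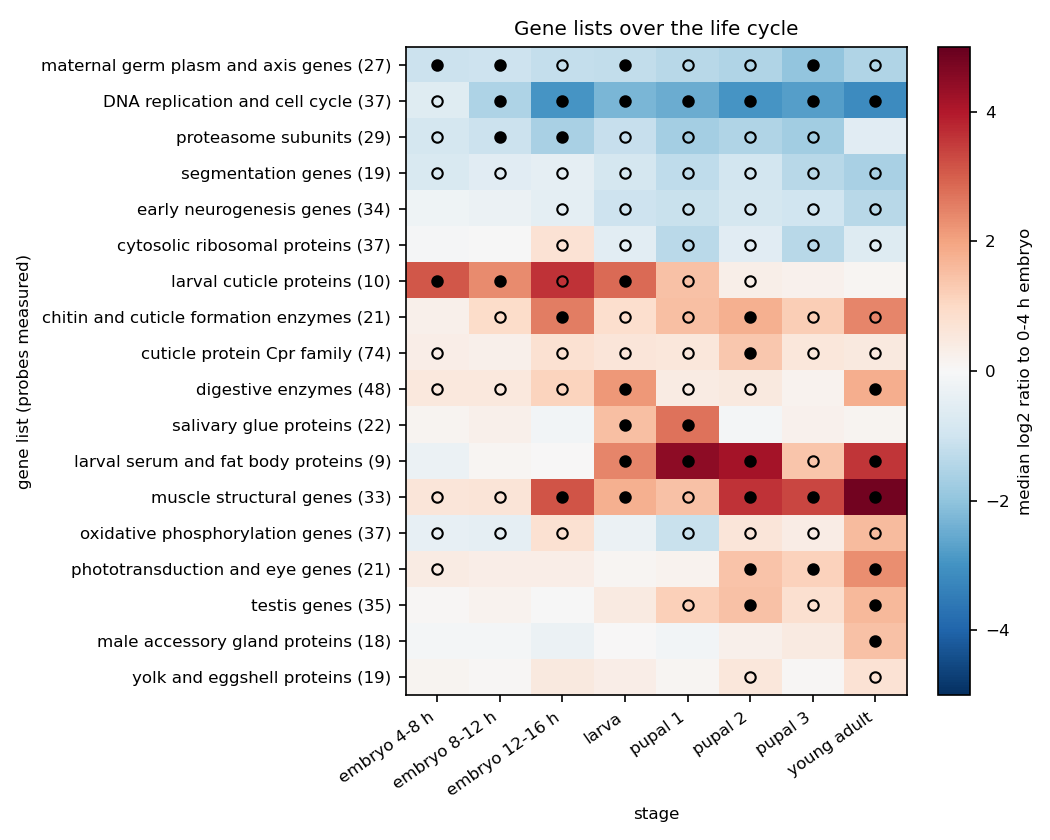
Median log2 ratio to the 0-4 h embryo of 18 gene lists (vertical axis, number of probes in brackets) at the 8 stages (horizontal axis); filled circles mark lists called by camera with the preset and the estimated correlation, open circles those called with the preset correlation alone. The muscle list reached its highest median, 4.83, in young adults, and the DNA replication and cell cycle list its lowest, -3.13, also there.

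Successive stages were then compared with each other in the same fit. The reference cancels there if it was the same RNA on all arrays, which is not stated. Between 8-12 h and 4-8 h embryos 3 probes passed (1076 at an unadjusted p under 0.05), 2 higher and 1 lower. The 1 named gene was CG31131, which fell by 3.68 ± 0.55 (n = 3 against 3 arrays, adjusted p = 0.0149). Its call ended without array a or b of 4-8 h or any array of 8-12 h, with the set of 4 arrays as a block and without that set, which leaves 1 array of 4-8 h. DNA replication and cell cycle genes as a list were lower, with a median of -0.95 over 37 probes, although 0 of them passed singly and 2 when adjusted over the list alone (adjusted p = 3.38e-13, or 0.0149 with an estimated correlation). Its largest members were fzy, an activator of the anaphase-promoting complex, at -2.25 ± 0.56 and PolA2 at -1.77 ± 0.58, neither of which passed. Both passed on scaling the arrays to one spread (adjusted p = 0.0283 and 0.0232), and fzy also with array weights (adjusted p = 0.022). The count was 0 without array a of 4-8 h or array b of 8-12 h, and 1 without array c of 8-12 h. It was 130 on scaling, 52 with array weights and 13 without the arrays with unlike duplicate spots. With only the arrays of both stages limma called 0 (1156 at an unadjusted p under 0.05). With the set of 4 arrays as a block, 1 probe passed, and 5 passed uncentred, of which 0% were higher, against 66.7%.

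From 8-12 h to 12-16 h, cuticle and muscle genes rose. TwdlN rose by 6.04 ± 0.84 (n = 3 against 3 arrays, adjusted p = 0.000225), TwdlD by 5.77 ± 0.73, Cpr51A by 5.39 ± 0.62, and the Osiris genes Osi19, Osi20 and Osi14 by 5.78 ± 0.81, 5.37 ± 0.82 and 5.23 ± 0.56. Muscle genes rose for 20 of 33 probes and fell for 0, 24 and 0 when adjusted over the list alone, with the LIM protein gene Mlp84B at 4.15 ± 0.50 and Prm at 3.93 ± 0.58 (adjusted p = 3.18e-19, or 0.0174 with an estimated correlation). Cuticle formation enzymes rose for 13 of 21 (15 when adjusted over the list alone), including serp at 3.88 ± 0.54, and pupal and adult cuticle proteins for 4 of 14 (6 when adjusted over the list alone), including Ccp84Ad at 3.67 ± 0.61 (adjusted p = 0.0221 and 0.0128 with an estimated correlation). Tom, of the Bearded family, fell by 3.78 ± 0.80. Cell cycle genes fell for 6 of 37 and 12 when adjusted over the list alone, among them Mcm2, of the replicative helicase, at -2.40 ± 0.59 (adjusted p = 1.47e-08, or 0.048 with an estimated correlation). The call of the cell cycle list (adjusted p = 0.301) and those of Prm and Mcm2 ended on scaling the arrays to one spread, those of Prm, Mcm2, serp and Ccp84Ad uncentred, that of Tom without 12-16 h array c, and that of Mcm2 also without the arrays with unlike duplicate spots, without 8-12 h array a or c or without 12-16 h array c. Limma called 1217 probes, 947 higher and 270 lower; the count was 650 without 8-12 h array a, 462 without 8-12 h array b, 1839 without 12-16 h array a and 575 without the set of 4 arrays. With only the arrays of these stages limma called 0 (2737 at an unadjusted p under 0.05). Uncentred, 105 passed and 50.5% were higher, against 77.8%.

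Larvae differed from 12-16 h embryos chiefly by lower values. Eig71Ee rose by 8.89 ± 0.66 (n = 3 against 3 arrays, adjusted p = 2.45e-07), Lsp2 by 7.64 ± 0.59, Fbp1 by 6.67 ± 0.47, Sgs7 by 6.22 ± 0.78 and Lcp1Psi by 6.12 ± 0.60. Glue proteins rose for 9 of 22 probes and fell for 0, 10 and 0 when adjusted over the list alone (adjusted p = 8.66e-08, or 0.0109 with an estimated correlation), a list call that ended with the probes whose duplicate spots were close. Digestive enzymes rose for 11 of 48 and fell for 2, 17 and 2 when adjusted over the list alone, with Jon99Cii at 4.92 ± 0.66 and Try29F at -3.44 ± 0.67 (adjusted p = 5.57e-11, or 0.0179 with an estimated correlation). Serum and fat body proteins rose for 4 of 9 and fell for 1, 6 and 1 when adjusted over the list alone; the 1 that fell was apolpp, at -2.17 ± 0.51 (adjusted p = 0.0221 with an estimated correlation). Among the lowest differences were -6.38 ± 0.80 for Osi19, -5.98 ± 0.61 for Cpr51A, -5.72 ± 0.94 for TwdlM and -5.68 ± 0.72 for TwdlD, while the lists of larval cuticle, pupal and adult cuticle and Cpr proteins did not pass (adjusted p = 0.317, 0.0664 and 0.418). Cuticle formation enzymes fell for 9 of 21 probes, 15 when adjusted over the list alone, with serp at -4.27 ± 0.53 (adjusted p = 1.86e-06, but 0.0788 with an estimated correlation). The call of apolpp ended uncentred, with scaling, with array weights, without larval array c or without the set of 4 arrays, and that of Try29F uncentred. Limma called 2434 probes, 625 higher and 1809 lower, with 1395 left without larval array c, 1269 without the set of 4 arrays and 11 with only the arrays of both stages. Uncentred, 318 passed and 55.7% were higher, against 25.7%.

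Between larvae and pupal stage 1 digestive enzymes fell. Eig71Ea rose by 6.46 ± 0.86 (n = 2 against 3 arrays, adjusted p = 0.000864) and Eig71Ej by 5.78 ± 0.79, the cuticle genes Cpr49Ah and Vajk4 by 5.53 ± 0.63 and 5.49 ± 0.62, fs(1)N, which acts in the eggshell and in terminal patterning, by 5.66 ± 0.75, and Mical, an actin-oxidizing enzyme, by 5.31 ± 0.90. Eig71Ee, at -0.42, did not pass (adjusted p = 0.88). Ecdysone response genes were higher as a list, with 0 of 30 probes past singly and 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0265, but 0.453 with an estimated correlation), a call that also ended uncentred, with the set of 4 arrays as a block or left out, and without larval array a or pupal 1 array b. Of 48 digestive enzyme probes 7 fell and 0 rose, 19 and 0 when adjusted over the list alone, with Jon65Aiv at -5.06 ± 0.83 and epsilonTry at -4.48 ± 0.84 (adjusted p = 9.17e-13, or 0.0128 with an estimated correlation). GstE6, a glutathione transferase, fell by 4.67 ± 0.89, and AcCoAS, the acetyl-CoA synthase gene, fell by 4.64 ± 0.77. Without the set of 4 arrays GstE6, Jon65Aiv, Mical and epsilonTry no longer passed, without pupal 1 array a AcCoAS, Jon65Aiv and epsilonTry, GstE6 with array weights or without pupal 1 array b, and epsilonTry uncentred or with that set as a block. Limma called 237 probes, 109 higher and 128 lower; the count was 147 without larval array b, 100 without pupal 1 array a, 817 without pupal 1 array b, 121 with the set of 4 arrays as a block and 81 without it. With only the arrays of both stages limma called 0 (1995 at an unadjusted p under 0.05). Uncentred, 18 passed and 38.9% were higher, against 46%.

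From pupal stage 1 to stage 2 glue genes fell and muscle and mitochondrial genes rose. Eig71Ee fell by 7.04 ± 0.78 (n = 3 against 2 arrays, adjusted p = 0.000239), and the differences were -6.50 ± 0.92 for Sgs7, -6.08 ± 0.86 for Eig71Ea and -6.01 ± 1.16 for Sgs4. Of 22 glue probes 5 fell and 0 rose, 15 and 0 when adjusted over the list alone (adjusted p = 2.11e-19, or 0.00186 with an estimated correlation). Scp1 rose by 5.18 ± 1.02, the cuticle gene Cpr76Ba by 4.40 ± 0.87 and Prm by 4.25 ± 0.91. Muscle genes rose for 7 of 33 and fell for 0, 20 and 0 when adjusted over the list alone, with fln at 3.54 ± 0.67 (adjusted p = 2.41e-23, or 0.0109 with an estimated correlation). Oxidative phosphorylation genes rose for 7 of 37 and fell for 0, 25 and 0 when adjusted over the list alone, with ATPsynCF6 at 2.84 ± 0.64 and ATPsynbeta at 2.51 ± 0.50 (adjusted p = 2.41e-23, or 0.0143 with an estimated correlation). Phototransduction genes were higher as a list, 0 of 21 singly and 3 when adjusted over the list alone, with Arr2 at 2.55 ± 0.67, which did not pass (list adjusted p = 0.0221 with an estimated correlation). Yp2 rose by 3.95 ± 0.53, and Yp1 was at 4.25 ± 1.06 without passing. On scaling the arrays to one spread Arr2 and Yp1 passed (adjusted p = 0.0484 and 0.0302), and Arr2 also without the arrays with unlike duplicate spots (adjusted p = 0.0176). With only the arrays of these stages limma called 0 probes (2244 at an unadjusted p under 0.05), Eig71Ee, Sgs7 and Eig71Ea included. Sgs4, Scp1, Prm, fln, Cpr76Ba, ATPsynCF6 and ATPsynbeta were lost without the set of 4 arrays, without pupal 1 array a, without pupal 2 array c and with pupal 2 arrays a and b averaged. These without Sgs4, and Yp2, were also lost uncentred. Without pupal 2 array b the 7 but fln, and without array a the 7 but fln and Scp1, no longer passed. ATPsynCF6 and Prm were lost on scaling, ATPsynCF6, ATPsynbeta and Sgs4 without the dye term, Prm, Scp1 and fln with array weights, and these 3 and ATPsynCF6 without the arrays with unlike duplicate spots. ATPsynCF6 was lost as well with run centring, with limit values kept and with the set of 4 arrays as a block. Limma called 152 probes, 107 higher and 45 lower; the count was 56 and 637 without pupal 1 array a or b, and 66, 45 and 19 without pupal 2 array a, b or c. Uncentred, 14 passed and 21.4% were higher, against 70.4%.

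Pupal stage 3 against stage 2 gave mostly falls. Yp2 fell by 4.15 ± 0.46 (n = 3 against 3 arrays, adjusted p = 0.000452), Fbp2, a fat body protein, by 3.64 ± 0.67, and the cuticle genes Vajk4 and Cpr49Ah by 3.57 ± 0.54 and 3.51 ± 0.55. Of 19 probes for yolk and eggshell proteins 3 fell and 0 rose, 5 and 0 when adjusted over the list alone (adjusted p = 1.57e-06, or 0.0388 with an estimated correlation). Serum and fat body proteins fell for 3 of 9 and 5 when adjusted over the list alone, with apolpp at -2.77 ± 0.52 and Fbp1 at -2.53 ± 0.48 (adjusted p = 1.59e-05, or 0.0373 with an estimated correlation). Cpr cuticle proteins fell for 3 of 74 and 17 when adjusted over the list alone (adjusted p = 1.66e-10, or 0.0103 with an estimated correlation). On the higher side ple rose by 2.64 ± 0.48 and Hsp70Bb, a heat shock chaperone, by 2.01 ± 0.42. Uncentred, none of these 8 genes passed; with arrays a and b of each stage averaged, or without pupal 2 array c, Yp2 alone did, and Hsp70Bb was lost without any 1 of the 6 arrays. Fbp1 and apolpp were lost without any 1 of these but pupal 2 array a, ple without any but pupal 3 array c, and Fbp2 without pupal 2 array b or pupal 3 array a or b. Without the set of 4 arrays Fbp1, Fbp2, apolpp, ple and Hsp70Bb were lost, on scaling Fbp1, ple and Hsp70Bb, without the dye term Fbp2, apolpp and Hsp70Bb, and with run centring Hsp70Bb. Limma called 81 probes, 7 higher and 74 lower. The count was 37, 21 and 23 without pupal 2 array a, b or c, and 25, 23 and 26 without pupal 3 array a, b or c. With only the arrays of both stages it was 18. With arrays a and b of each stage averaged it was 1, and with array weights 1512. Uncentred, 7 passed and 100% were higher, against 8.64%.

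Young adults against pupal stage 3 gave mostly rises. Yp2 rose by 5.97 ± 0.46 (n = 3 against 3 arrays, adjusted p = 9.16e-07), BomBc2 by 5.94 ± 0.85, Ebp, of the ejaculatory bulb, by 4.83 ± 0.58 and the protease gene Jon65Aiii by 4.42 ± 0.51. Digestive enzymes rose for 10 of 48 probes and fell for 0, 23 and 0 when adjusted over the list alone, with Amy-p at 4.26 ± 0.92 (adjusted p = 1.07e-13, or 0.0109 with an estimated correlation). Male accessory gland proteins rose for 7 of 18, 9 when adjusted over the list alone, with Acp36DE at 3.66 ± 0.62 and Acp62F at 3.33 ± 0.57 (adjusted p = 5.2e-07, or 0.00675 with an estimated correlation). Phototransduction genes rose for 3 of 21 (7 when adjusted over the list alone), with Gbeta76C at 3.84 ± 0.48, oxidative phosphorylation genes for 5 of 37 (20), with ATPsynB at 1.99 ± 0.38, and yolk and eggshell proteins for 3 of 19 (7), with Yp3 at 3.57 ± 0.46, where brackets give counts adjusted over the list alone (adjusted p = 0.0109, 0.0464 and 0.0415 with an estimated correlation). TpnC4 fell, at -3.44 ± 0.78, as did the cuticle gene Cpr64Ac, at -3.04 ± 0.64, and the early patterning genes cad and zen, at -2.75 ± 0.48 and -2.54 ± 0.53. Uncentred, Acp36DE, Acp62F, Amy-p, Gbeta76C, ATPsynB, Yp3, TpnC4, Cpr64Ac, cad and zen no longer passed; scaling ended the calls of ATPsynB, TpnC4, Cpr64Ac, cad and zen, and averaging arrays a and b of pupal stage 3 those of ATPsynB, Acp62F, Amy-p, TpnC4, Cpr64Ac and zen. Amy-p was lost without any 1 of the 6 arrays but adult b, TpnC4 without any pupal 3 array or adult c, Cpr64Ac without pupal 3 array a or b or adult a or b, zen without pupal 3 array b or c or adult b or c, and ATPsynB without pupal 3 array c or adult a. Without the set of 4 arrays TpnC4 and Cpr64Ac were lost, and without the dye term ATPsynB. Limma called 282 probes, 261 higher and 21 lower. The count was 105, 111 and 112 without pupal 3 array a, b or c, and 127 without adult array c. With only the arrays of both stages it was 32. On scaling it was 55, with arrays a and b of pupal stages 2 and 3 averaged 57, and with array weights 1670. Uncentred, 12 passed and 100% were higher, against 92.6%.

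**Figure D3:**
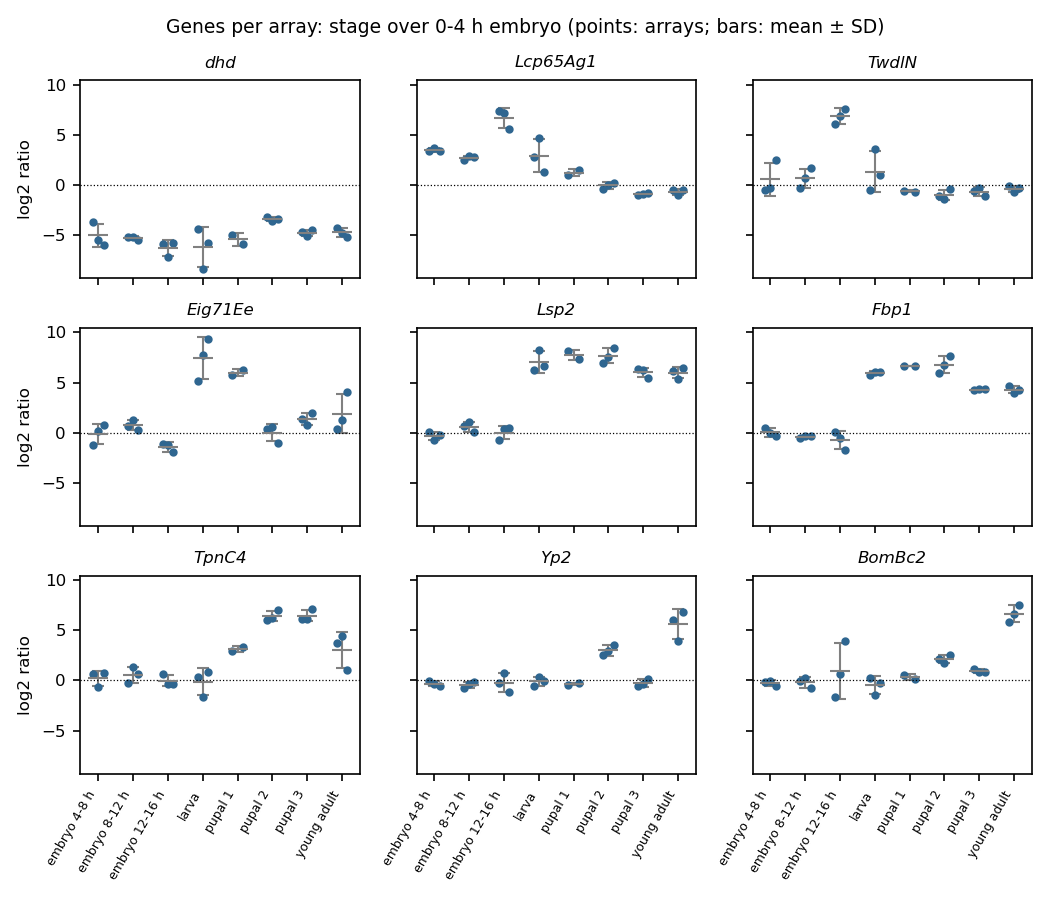
Centred log2 ratio to the 0-4 h embryo (vertical axis) on each array at the 8 stages (horizontal axis) for 9 genes, 1 probe per gene (the one with the widest range); points are arrays and grey bars the mean ± SD of a stage's 2 or 3 arrays. dhd lay below 0 on all 23 arrays, TwdlN peaked at 12-16 h, Eig71Ee in larvae and pupal stage 1, and Yp2 at pupal stage 2 and in adults.

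**Figure D4:**
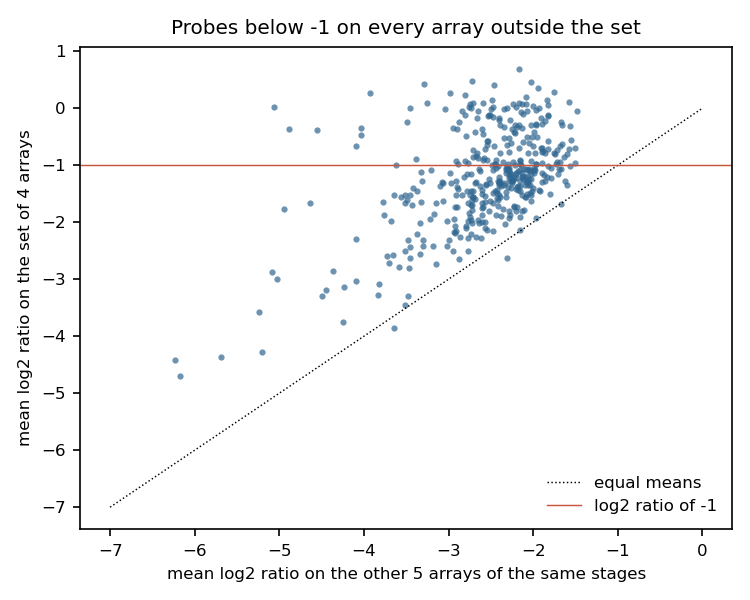
Mean log2 ratio of 414 probes that lay below -1 on every one of 19 arrays, with a median below -2, on the 4 arrays that stood apart (vertical axis) against the 5 other arrays of the same stages (horizontal axis); the dotted line marks equal means and the red line -1. The medians of the 2 means were -1.21 and -2.42.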

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

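All tests of explanations in this part were chosen after the results they weigh had been seen, and the counts over other groupings of the arrays were planned. Several probes passed against the reference at both of 2 successive stages, in opposite directions, with a difference that also passed. There were 18 such probes from 8-12 h to 12-16 h (Adh and VhaSFD among their genes), 120 from 12-16 h to larvae (Eig71Ee, Sgs1, fkh), 20 from larvae to pupal stage 1 (Adh, GstE6, Ogdh), 23 from pupal stage 1 to stage 2, of which 21 went from lower to higher (ATPsynbeta, blw, Idh3a, mAcon1), 13 from pupal stage 2 to 3, all from higher to lower (miple2, Upf3), and 22 from pupal stage 3 to adults, of which 20 went from lower to higher (ATPCL, Galk, UGP). These genes were named after their values were seen. Whether a probe lies above or below 0 depends on the centring. Uncentred, 3 probes rose from pupal stage 1 to stage 2, 0 fell from stage 2 to 3 and 12 passed from stage 3 to adults. The 13 falls thus all ended uncentred, as did most of the 21 rises.

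Array c of pupal stage 1, which held 1-channel signals and entered no comparison, was also looked at. Its 119 probes that lay above 4 on arrays a and b of that stage had a median log2 signal of 9.07, against 8.69 for 14875 probes near 0 there, a difference of 0.38.

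The first pattern is the set of 4 arrays (4-8 h a and b, 8-12 h a, larva a) that read near 0 for probes far below 0 elsewhere: of 414 probes below -1 on all 19 other arrays, with a median there below -2, 72 were within 1 of 0 on all 4, with medians of -0.10 there and -2.57 elsewhere. These 4 also had the narrowest spread of the 23 arrays. Their interquartile ranges were 1.05, 1.03, 0.98 and 1.12, the next lowest being 1.20 (8-12 h c). A fixed limit of 1 around 0 picks narrow arrays more readily. A reference RNA that differed cannot be told apart: it would move all probes of a gene alike. Of 11 probe pairs (7 genes) within 1 of each other elsewhere, 4 were over 1 apart on the set, while the others stayed within 1. The 4 were of Marf1 (4.3), Parp1 (1.02) and MED26 (1.82 and 1.95, sharing a probe), so the pairs are not independent. One factor shrinking every value would leave no excess after scaling the arrays to one spread. On the set 22.7% of the 414 probes then still lay above -1, against at most 2.09% for 70 other sets of 4 arrays with the same dye. But the set had been picked for its probes near 0, and the 414 hold the 72 so picked, so the comparison cannot decide. Scaling brought the median of the 414 on the set from -1.21 to -1.97, against -2.38 then on the other arrays. This is the last of 3 forms of that test, all written after the values were seen. The first used only the 72 probes, whose choice fixed its outcome. The second, with a limit of 25% and no other sets, would have kept the factor. Such a factor thus stays open. Weak signal over background cannot be told apart either: of 127 named probes above 3 on larval arrays b and c, 39 (30.7%) were near 0 on array a, but array a has a lower spread and the other dye, so this share decides nothing. Intensities, which would show it directly, were not used here, and a biological difference between replicates was not tested.

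The second pattern is the yolk genes at pupal stage 2, with Yp2 at 4.39, against 0.44 at stage 1 and 0.24 at stage 3. Adult flies mixed in would bring other adult transcripts. But 17 genes above 4 in adults and below 1 at pupal stages 1 and 3 lay a median of -3.5 from their adult value at stage 2. Their interquartile range was 1.49, the median of the 4 yolk probes was -1.89, and 16 of the 17 lay below that. The 2 medians were only just over 1 interquartile range apart. The yolk probes also had no limit in adults: Yp1 (3.52) and Yp3 (3.77) lay below 4 there, and the probes of Yp2 were at -1.83 and -2.6. The comparison is thus not like for like and cannot exclude adult admixture. Most of the 17 lay higher at stage 2 than at both stages 1 and 3, the direction that some adult RNA would give. Among these were CG16826 (4.05 in adults) at 2.89, CG14645 (4.8) at 2.63, BomBc2 (6.79) at 2.27 and Amy-p (4.99) at 1.95. The rest did not, such as Nplp3 (4.66) at -0.03. Whether pupal stages 2 and 3 were exchanged cannot be told apart from the labelled order: on a line from stage 1 to adults the 2 stages differed by 0.019 (means 0.565 and 0.546) and their arrays overlapped. A difference between the pupae stays open and untested; more females at stage 2 would lower testis genes there, but these also fell as a list from stage 2 to 3 (adjusted p = 0.00165, but 0.112 with an estimated correlation, and lost with close duplicate spots).

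The third pattern is the Lcp65A cuticle genes at 4-8 h, where 7 of 11 probes rose. Admixture of 12-16 h embryos would bring their other high genes. Of these, 68 genes above 5 at 12-16 h lay a median of -4.79 from that value at 4-8 h (interquartile range 1.11). The median was -1.19 for the 7 Lcp65A probes that rose, and 68 of 68 lay below that. For larvae the median was -3.79 over 36 genes above 4 there, against 0.07 for the 7 probes. But the 7 were picked for passing at 4-8 h and had no limit at the later stage, which favours small distances. The other high genes thus lay far below their later values at 4-8 h, but the comparison with Lcp65A cannot decide on admixture. Whether near-identical copies share signal cannot be told apart from joint regulation: the probes correlated at 0.561 to 0.995 over the stages and lay up to 4.46 apart at 12-16 h, and no probe sequences were used here. Expression in the young embryo itself stays among the open explanations.

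Other groupings of the arrays gave fewer probes. For the F-test across the 8 stages, 1 of 100 groupings, the real one, reached 5011 probes, the highest other being 11. Arrays of a stage were thus more alike than randomly grouped arrays. But in other groupings the stage differences enter the residuals, which can lower the counts, and arrays of a stage may be technical repeats. The comparison thus does not say how many of the 5011 probes are due to chance. Of the list tests between successive stages with the preset correlation, 88 passed, but 18 of 100 groupings gave as many, the highest 111. Chance can thus not be excluded for that number. With the estimated correlation 21 passed, which 1 of 100 groupings reached, the highest other being 2. In other groupings, however, the stage differences enter the residuals that give this correlation, which can lower the calls. That comparison thus cannot decide on chance for these lists. For 2 successive stages of 3 arrays each the 10 splits are too few for a share under 0.05. The real values and the highest of the other splits were 3 and 1 (8-12 h against 4-8 h), 1217 and 0 (12-16 h against 8-12 h), 2434 and 128 (larvae against 12-16 h), 81 and 0 (pupal stage 3 against 2) and 282 and 1 (adults against pupal stage 3), each real value reached by 1 of the 10 splits.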

How the results depend on the processing

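Of 198 named gene values, passing or not, 34 lost their call uncentred, 13 scaled (4 gained one), 7 without dye term and 26 without the set of 4 arrays; 0 reversed. Of 240 list calls 216, 215, 210 and 209 held, 141 of 217 with close duplicate spots, 219 with 1 value per gene, and 61 with the estimated correlation. Proteasome subunits reversed from 8-12 h to 12-16 h on scaling (0.24, adjusted p = 0.28) and from larvae to pupal stage 1 without dye term (0.17, adjusted p = 0.524); neither passed. A robust prior, other limits on missing values, a minimum log2 of 1 and kept limit values moved no count beyond 1.5 times. Signal over background could not be weighed without intensities, and the cause of shifts was not tested. All alternatives listed at the start were run. Run centring, kept limits, close or unlike duplicate spots, averaged arrays and the set of 4 were chosen after the data were seen.

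Other counts of probes (stages over the reference, then successive stages named by the later one) were as follows. Uncentred: 4-8 h 198, 12-16 h 14518, pupal 2 16603, pupal 3 4267; then 8-12 h 5, 12-16 h 105, larvae 318, pupal 1 18, pupal 2 14, pupal 3 7, adults 12; F-test 9757, named over unnamed 1.442. Scaled: 4-8 h 3801, 8-12 h 4832, pupal 1 3497, then 8-12 h 130, 12-16 h 572, larvae 1000, adults 55. No dye term: 4-8 h 643, 8-12 h 1372, pupal 1 3687, then larvae 1617, pupal 2 78, pupal 3 32, F-test 3335. Array weights: 4-8 h 3986, 8-12 h 4206, 12-16 h 4130, pupal 2 11494, pupal 3 13672, then 8-12 h 52, 12-16 h 776, larvae 594, pupal 1 40, pupal 3 1512, adults 1670, F-test 8344. Unlike duplicates left out: 4-8 h 3435, 8-12 h 3916, then 8-12 h 13, pupal 1 416, pupal 2 252, pupal 3 251. Pupal 2 and 3 arrays a and b averaged: pupal 2 3445, pupal 3 4368, then pupal 1 92, pupal 2 21, pupal 3 1, adults 57, F-test 3174. Close duplicates: adults 5442, then 8-12 h 5, pupal 3 140, ratio 1.314, lists 155. Run centring: 8-12 h against 4-8 h 5.

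The set of 4 arrays as a block gave 1032 at 4-8 h, then 8-12 h 1 and pupal 1 121. Left out, which leaves 1 array of 4-8 h, it gave 4-8 h 125, 8-12 h 1251, then 8-12 h 0 (limma), 12-16 h 575, larvae 1269, pupal 1 81, pupal 2 56, pupal 3 35, adults 160, F-test 2754. Only the arrays of the stages compared gave, by limma, 4-8 h 16, 8-12 h 521, 12-16 h 2110, larvae 0 (6078 at an unadjusted p under 0.05), pupal 1 730, then 8-12 h 0 (1156), 12-16 h 0 (2737), larvae 11, pupal 1 0 (1995), pupal 2 0 (2244), pupal 3 18, adults 32.

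Leaving out each array of the compared stages gave 331 to 764 at 4-8 h, 863 to 1280 at 8-12 h, 5508 to 7093 at 12-16 h, 3179 to 5424 in larvae, 2078 to 4536, 3637 to 4259 and 4728 to 5511 at the pupal stages and 6123 to 6537 in adults. Between successive stages it gave 0 to 2, 462 to 1839, 1395 to 3276, 100 to 817, 19 to 637, 21 to 37 and 105 to 206. The F-test gave 3997 to 5724, named over unnamed 2.166 to 2.502, lists 227 to 245.

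The replicate letter as a block left 63 probes between pupal stages 3 and 2, 4908 in the F-test and 240 of 240 list calls, and ended the named calls of Hsp70Bb (pupal 3 against 2) and TpnC4 (adults against pupal 3) alone. Arrays sharing a letter had a median r of 0.004, and 6 of 23 arrays lay closest to their own letter.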

Other observations

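The tests in this part were planned, apart from values named after they were seen. Further list results are given here, with more on the proteasome list described above. Glycolysis and citrate cycle genes were lower for 8 of 19 probes at 4-8 h and higher for 15 in adults, 9 and 15 when adjusted over the list alone, with Gapdh1 at -2.72 ± 0.29 in the first and the hexokinase gene Hex-C at 3.42 ± 0.37 in the second (camera adjusted p = 7.92e-07 and 5.2e-07, with adjusted p = 0.159 and 0.153 with an estimated correlation). Early neurogenesis genes fell for 16 of 34 probes in larvae and 20 in adults, 19 and 25 when adjusted over the list alone, with mira, which localizes determinants in neuroblasts, at -2.25 ± 0.38 and -3.81 ± 0.38 (adjusted p = 0.101 and 0.0674 with an estimated correlation). Segmentation genes fell for 14 of 19 probes in adults, 14 when adjusted over the list alone, led by hb at -3.40 ± 0.50 (adjusted p = 0.0674 with an estimated correlation). Proteasome subunits, lower as a list at each stage from 4-8 h to pupal stage 3 (with an estimated correlation at 8-12 h and 12-16 h alone, and at adjusted p = 0.0678 at 4-8 h), rose for 4 of 29 probes from pupal stage 3 to adults, 14 when adjusted over the list alone, with Rpn7 at 2.45 ± 0.58 (adjusted p = 1.44e-12, but 0.0511 with an estimated correlation).

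Among immune genes, 10 of 17 probes for antimicrobial peptides and immune recognition were higher in adults and 2 lower, 10 and 2 when adjusted over the list alone, with the complement-like Tep3 at 4.02 ± 0.56 and the attacin gene AttB at 3.11 ± 0.50 (adjusted p = 0.021, but 0.117 with an estimated correlation), a list call that also ended without adult array a or with close duplicate spots. Of the heat shock list, Hsp26 was at -3.89 ± 0.58 at 4-8 h and -4.41 ± 0.58 at 8-12 h, and Hsp27 at -5.55 ± 0.49 at 12-16 h, where the list did not pass (adjusted p = 0.163). At 8-12 h its adjusted p was 0.0139, but 0.343 with an estimated correlation. Among the 8 heat shock and chaperone probes of 11 that did not pass at 4-8 h was Hsf, their transcription factor, at -1.16 ± 0.36 (list adjusted p = 0.0025, but 0.255 with an estimated correlation).

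Adult array b differed from its partners in a yolk gene: Yp1 was at 0.84 there against 4.94 and 4.74 on arrays a and c.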
